A study of Mus musculus with 4 samples.

How the data were processed

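The series holds 4 RNA-seq libraries of primary mouse microglia, 2 mock and 2 treated with LysoPS for 4 h. Per the labels' protocols, RNA was extracted with Trizol, mRNA was selected with poly-T beads, and libraries were made with a Hieff NGS MaxUp Dual-mode kit and sequenced paired-end on MGISEQ2000 instruments. The treatment label says that 1 replicate was treated, while 2 samples carry LysoPS in their own labels, and the sample labels were followed. Whether the libraries keep strand was not given in the sources used here, so reads of overlapping and antisense genes may not have been told apart.

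Per the submitters' processing notes, the tools were FastQC 0.11.2, Trimmomatic 0.36, HISAT2 and StringTie and the genome build was GRCm38. Their parameters, the annotation release and the program that made the gene counts were not given in the sources used here. Per the file headers, 1 table gives for each of 51826 gene models and each library a count, a TPM and an FPKM value. The deposited counts were whole numbers without normalization. Low even values were more frequent than odd ones (over all libraries, 3582 values of 4 against 2547 values of 3), so intervals that treat each count as independent may be too narrow. The deposited TPM columns summed to between 999725 and 999826 and were not tested. The deposited FPKM values were used only to derive the transcript length that counts and FPKM together imply for a gene in each library. A variation by over 1.2 times was taken as a sign that reads may have been assigned to different transcript models in different libraries, which was not tested on reads. Of the gene models, 48616 (93.8%) had the same coordinates in GENCODE M21, which supplied lengths and GC content, and 93 symbols belonged to more than 1 model. Some counts were shared between near-identical loci. The chromosome 1 copy Gm28437 (24613189 to 24613971) held 119703 counts in mock replicate 1, and mt-Co3 held 120719.

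Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr with its defaults (a minimum count of 10), libraries were scaled by TMM (factors from 0.966 to 1.04), and the quasi-likelihood F test compared LysoPS with mock with 2 residual degrees of freedom. P-values were two-sided and adjusted by Benjamini-Hochberg over the 19057 tested genes with a threshold of 0.05. The biological coefficient of variation was 0.150. CPM values use TMM-scaled library sizes, and log2 CPM used a prior count of 2. A gene without counts in a group was given a bound from 3 counts over that group, and a gene with 1 to 3 counts a 95% counting interval. Library totals ranged from 30001098 to 45193959 counts.

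Of 33 gene lists, 32 had at least 5 tested genes and entered camera with a preset inter-gene correlation of 0.01, adjusted over the lists. In all, 21 lists passed, 17 higher and 4 lower. With a correlation estimated per list none passed (lowest adjusted p 0.257; 5 had an unadjusted p under 0.05), and by fry, which asks whether a list's genes move on balance one way and does not compare them with other genes, 19 passed. The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took, among genes past the threshold with a mean of at least 5 CPM in the higher group and both LysoPS libraries on the same side of both mock libraries, the 10 largest changes and the 5 smallest p-values in each direction. It added Tnf, Il1b, Il6, Ccl2, Nos2 and Gpr34, and up to 4 members of each list with the smallest p. Il18, Itgam, Cxcl11, Csf1r, C1qa and, in the closing part, a few further genes were named after their values were seen. Some genes that the rule takes are not reported here.

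The fit was tested on simulated counts for LysoPS against mock with 18504 genes. It recovered 13 of 66 genes changed by 1.5-fold, 50 of 67 changed by 2-fold and 65 of 66 changed by 4-fold, and 9 of its 137 calls were false. The data gave 4854 calls. With fewer changed genes the p-value needed for a call was smaller in the simulation, so its recovery rates may not apply to the data. In a separate simulation of sets with 19057 genes, all 5 changed sets and none of 20 unchanged sets were called, and 5 were recovered with an estimated correlation. Its genes were drawn independently and every member of a changed set rose by 2-fold, so correlation between genes was not simulated.

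The alternatives were DESeq2 size factors, no filter and a stricter filter (5 CPM in 2 libraries), DESeq2 1.42.0, limma-voom, robust dispersion, a replicate block, each library left out in turn, a fold threshold of 1.5, an estimated correlation and fry. Added after the data were seen were the removal of each library's trend on transcript length and GC content (splines with 5 degrees of freedom), a restriction to gene models with stable read assignment, and the removal of mitochondrial genes and their copies. Stable models had at least 20 counts in each library and an implied length varying by under 1.2 times. Their replicates also had to lie under 2-fold apart in CPM within each group. Choosing genes for close replicates can make p-values too small, so a pass in that set alone is weak evidence. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.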

Results

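The series measured messenger RNA in cultured mouse microglia, the resident macrophages of the brain, with and without lysophosphatidylserine (LysoPS). LysoPS is a phospholipid that has lost 1 of its fatty acid chains and is a known ligand of the receptor GPR34, which the series title names. The cells came from newborn C57BL/6 brains, grew for 2 weeks as a mixed glial culture and were then shaken off. There were 4 libraries in 2 groups, 2 mock and 2 treated with LysoPS for 4 h. The mock libraries held 30001098 and 41572340 counts, and the LysoPS libraries held 34689045 and 45193959. Whether the replicates came from separate cultures or animals was not stated, so every p-value below measures the spread between these samples only, and that spread may be technical. Values are normalised read counts (CPM, using TMM-scaled library sizes), given as mean ± SD over the 2 libraries of a group. Log2 fold changes compare LysoPS with mock.

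Replicates of a group lay closer to each other than to the other group. The correlation of log2 CPM across genes was 0.987 between the mock libraries and 0.985 between the LysoPS libraries, and it ranged from 0.953 to 0.963 between groups. The first principal component, with 71.5% of the variance, separated mock from LysoPS, and the second, with 15.8%, separated replicates. On the second, both replicate 1 libraries were positive (16.1 in mock, 29.8 in LysoPS) and both replicate 2 libraries negative (-10.4 and -35.5). The chi-square statistic per degree of freedom between replicates was 17.4 in mock and 27.2 in LysoPS. Mitochondrially encoded genes took 5.81% and 5.72% of the counts in mock and 5.49% and 5.60% in LysoPS.

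The comparison of the groups asked what LysoPS does to the transcripts of these primary microglia cultures. They also held RNA of other cells. In mock the astrocyte marker Gfap stood at 5827 CPM and the fibroblast marker Fn1 at 4658. The macrophage genes Lyz2, Csf1r and C1qa stood at 2814, 336 and 318 CPM. Changes below are therefore those of the cultures, and which cells they came from was not tested. After 4 h the pro-inflammatory cytokine Tnf stood at 178 ± 1.74 CPM against 3.58 ± 0.544 in mock (log2 fold change 5.65, adjusted p = 0.000248). Il1b, which encodes interleukin-1 beta, rose from 0.144 ± 0.0723 to 18.1 ± 1.49 CPM, and the monocyte attractant Ccl2 from 3.08 ± 0.275 to 152 ± 26.0 CPM. The anti-inflammatory cytokine Il10 had no count in either mock library and 17.1 ± 0.967 CPM after LysoPS, which is at least 425-fold higher (floor of 3 counts over the group). Gpr34 itself fell from 24.7 ± 0.0385 to 2.09 ± 0.634 CPM (log2 fold change -3.55, adjusted p = 0.000965). Of 19057 genes tested, 4854 (25.5%) changed at an adjusted p under 0.05, 2447 of them higher and 2407 lower, and 1485 of these differed by at least 2-fold (823 higher, 662 lower). Without mock replicate 1 the count was 2223, and without mock replicate 2 it was 2165. Against a fold change of 1.5 as the null, 1064 genes passed (683 higher, 381 lower).

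Gpr34 (ENSMUSG00000040229) lies on the plus strand of chromosome X from 13632089 to 13640858 in GRCm38. Its libraries held 1827 counts in mock and 166 after LysoPS. Tnf (ENSMUSG00000024401) lies on the minus strand of chromosome 17 from 35199381 to 35202007, and Il10 (ENSMUSG00000016529) on the plus strand of chromosome 1 from 131019845 to 131024974. Il6, another pro-inflammatory cytokine, had 2 counts over the mock libraries and reached 4.21 ± 0.258 CPM, a ratio of 155 with a 95% counting interval from 42.6 to 1285 (adjusted p = 0.00142). Both mock counts came from mock replicate 2, so none remained without it, and without mock replicate 1 the fitted log2 fold change went from 7.13 to 6.41. Nos2, the inducible nitric oxide synthase, reached 2.13 ± 1.21 CPM from 0.0462 ± 0.0654 (log2 fold change 5.23, adjusted p = 0.0135). Its mock libraries held 0 and 4 counts and its LysoPS libraries 156 together. The log2 fold change of Nos2 was 4.47 without mock replicate 1 and 4.51 without LysoPS replicate 1. Without mock replicate 2 no mock count remained, so no fold change is given. Counting intervals and floors cover counting error only.

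Among the 10 largest rises were Acod1, which makes itaconate (log2 fold change 8.28, from 0.769 ± 0.794 to 219 ± 1.14 CPM), the chemokines Cxcl2 (7.23) and Cxcl3 (6.77), and the formyl peptide receptors Fpr1 (7.36) and Fpr2 (to 23.6 ± 3.87 CPM). Their mock levels were low, with Acod1 at 1.33 and 0.208 CPM in mock replicates 1 and 2, and the size of these rises depended on the mock library left out. Without mock replicate 2 the log2 fold changes were 7.36 for Acod1, 6.58 for Cxcl2, 5.57 for Cxcl3, 6.58 for Fpr1 and 5.79 for Fpr2. Without mock replicate 1 they were 10.02 for Acod1, 8.05 for Cxcl2 and 8.58 for Fpr1, while Cxcl3 and Fpr2, with 4 and 13 counts in that library and 0 in the other, had no mock count left. Gpr18, a G protein-coupled receptor, rose by 7.38 on the log2 scale. The myeloid receptor Cd300e and the processed pseudogene Gm6977 had no counts in mock and were at least 169-fold and at least 151-fold higher, with Gm6977 at 9.47 and 3.52 CPM in LysoPS replicates 1 and 2. The smallest p-values among higher genes included those of the integrin subunit Itgal (4.30), the collagenase Mmp13 (4.42), Tnf and the bacterial lipoprotein receptor Tlr2 (3.03, from 21.6 ± 0.0298 to 176 ± 2.24 CPM).

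Among the 10 largest falls were the transporter Slco2b1 (log2 fold change -3.51, from 53.1 ± 2.63 to 4.64 ± 0.906 CPM), the T cell costimulatory receptor Cd28 (-3.08), the aminopeptidase Xpnpep2 (-2.77) and the urokinase Plau (-2.36, from 132 ± 5.67 to 25.7 ± 1.24 CPM). The smallest p-values among lower genes also included E-cadherin Cdh1 (-2.16), Itih2 (-1.95, from 393 ± 8.18 to 102 ± 4.95 CPM) and Rasgrp3 (-2.15). The potassium channel Kcna2 (-3.67), the deubiquitinase Usp49 (-2.50), Zfx (-2.42) and the ectonucleotidase Entpd1 (-2.27) fell as well, but the transcript length implied by their deposited counts and FPKM differed between libraries by 2.95, 2.12, 1.52 and 1.47 times. A Map2k7 model on chromosome 8 (4238865 to 4251423) went from 12.8 ± 1.27 CPM to no counts. It overlaps a second Map2k7 model on the same strand, and the sum of both was 20.7 ± 0.895 CPM in mock and 36.2 ± 20.3 CPM after LysoPS.

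**Figure D1:**
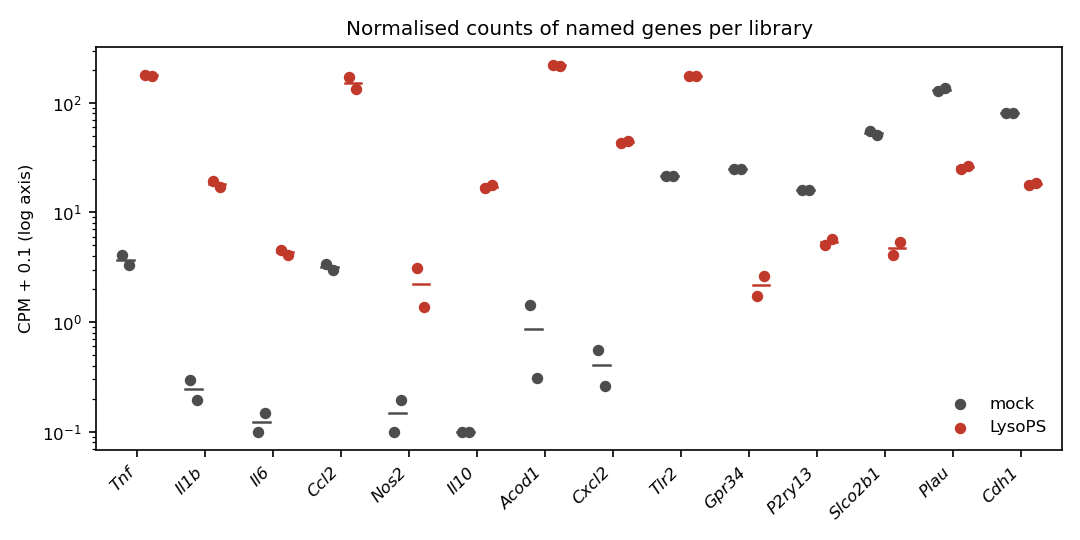
CPM of 14 genes in each library on a log axis after adding 0.1, with mock in grey and LysoPS in red; points are libraries and lines are the means of 2. In all 5 genes on the right, Gpr34 to Cdh1, both LysoPS libraries lie below both mock libraries, and in the other genes above them; Gpr34 goes from 24.7 to 2.09 CPM.

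Transcripts of secreted inflammatory signals and of their regulators rose as groups. Of 14 tested inflammatory cytokines, 10 were higher and 1 (Il18) lower, or 11 and 2 adjusted over the list alone, with a median log2 fold change of 1.65. The list included Ebi3, a subunit of interleukins 27 and 35 (3.08), and Il1a (5.91). Its adjusted p was 9.3e-10 by camera and 0.279 with an estimated correlation. Of 20 chemokines, 17 were higher and none lower (18 and 0 adjusted over the list alone). Cxcl1, a neutrophil attractant, rose by 6.66, and Ccl3 rose from 21.2 ± 1.30 to 394 ± 37.8 CPM. Their median was 4.40, or 4.28 with Cxcl11, which had no mock counts, at its bound, and the adjusted p of 4.01e-23 became 0.279 with an estimated correlation. Of 25 NF-kappaB target and feedback genes, 23 were higher (23 adjusted over the list alone) and none lower, with a median of 1.91, among them the inhibitor-like Nfkbiz (4.17), the RNase Zc3h12a (3.48) and the kinase-dead Irak3 (3.61). Tnip3 rose by 4.51, with an implied length that varied by 1.24 times between libraries. The list's adjusted p was 1.36e-27, and 0.257 with an estimated correlation. In the same libraries the astrocyte markers fell, with a median of -0.83. Of 31 gene models for general microglia and macrophage genes, a list written after some of its values were seen, 22 were higher and 3 lower, with a median of 1.05.

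Receptors and effectors of innate sensing rose too. Of 24 innate sensing receptors and adaptors, 17 were higher and 7 did not pass (17 higher adjusted over the list alone), with a median of 0.98. The lectin receptors Clec4e (3.92) and Clec4d (2.84) and the lipopolysaccharide coreceptor Cd14 (2.03, from 40.7 ± 0.664 to 167 ± 18.2 CPM) stood beside Tlr2. The implied length of Clec4e varied by 1.35 times. Of 15 inflammasome and pyroptosis genes, 10 were higher and 1 lower (12 and 1 adjusted over the list alone), with a median of 1.02, among them the inflammatory caspases Casp4 (3.16, implied length varying by 1.26 times) and Casp1 (1.84). The adjusted p-values were 1.16e-13 for sensing and 7.51e-08 for the inflammasome, and each was 0.257 with an estimated correlation. Of 30 type I interferon response genes, 26 were higher and none lower (28 and 0 adjusted over the list alone), with a median of 1.46. Cxcl10 (4.35), Gbp3 (1.97), the antiviral Ifit1 (1.72) and Oas1a (1.95) were examples, and the adjusted p was 7.78e-18, or 0.279 with an estimated correlation. Of 19 antigen presentation genes, 14 were higher and none lower (17 and 0 adjusted over the list alone), with a median of 0.79. They included the class II genes H2-Aa (1.97) and Cd74 (2.58) and the class I light chain B2m (1.14, from 616 ± 21.4 to 1357 ± 91.6 CPM), with an adjusted p of 2.61e-10, or 0.362 with an estimated correlation. The fall of the astrocyte markers (median -0.83) and the rise of general microglia and macrophage genes (median 1.05) accompanied these groups.

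Anti-inflammatory genes and early response genes moved mostly upward. Of 19 anti-inflammatory and alternative activation genes, 10 were higher, 2 lower and 7 not past the threshold (11 and 3 adjusted over the list alone), with a median of 0.80. Beside Il10 these were the scavenger receptor Msr1 (2.18), the cytokine signalling inhibitor Socs3 (2.05) and the receptor chain Il4ra (1.80). Of 28 immediate-early and ERK feedback genes, 16 were higher and 1 lower (17 and 1 adjusted over the list alone), with a median of 0.56. The transcription factor Junb rose from 28.3 ± 1.34 to 129 ± 0.459 CPM, the phosphatase Dusp2 by 3.35, Plaur by 0.90 and Ier3 by 1.13. Adjusted p-values were 1.04e-05 and 1.85e-06, and 0.279 and 0.390 with an estimated correlation. Of 16 cAMP and CREB responsive genes, 2 were higher, 2 lower and 12 did not pass (3 and 3 adjusted over the list alone; adjusted p = 0.743). The phosphodiesterase Pde4b (1.51) and the kinase Sik1 (0.93) rose, and the G protein regulators Rgs2 (-1.16) and Rgs1 (-1.49) fell, and without LysoPS replicate 1 Rgs1 stood at -1.43 but lost its call (adjusted p = 0.0534). Of 21 FOXO target genes, 5 were higher and 8 lower (5 and 11 adjusted over the list alone; adjusted p = 0.180), with Bcl6 (1.16) and Trib1 (0.99) up and Fbxo32 (-1.19) and Txnip (-0.90) down. Beside these lists, the medians were -0.83 for astrocyte markers and 1.05 for general microglia and macrophage genes.

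Microglial identity genes went both ways. Of 22 tested homeostatic microglia markers, 5 were higher, 9 lower and 8 did not pass (6 and 9 adjusted over the list alone), with a median of -0.13 and an adjusted p of 0.295. Besides Gpr34, the purinergic receptor P2ry13 fell (-1.59, from 15.9 ± 0.0736 to 5.28 ± 0.457 CPM), while Fcrls rose by 0.90. General microglia and macrophage genes had a median of 1.05 in the same libraries and astrocyte markers one of -0.83. The rise of Fcrls was thus no larger than that of general microglia genes, and the homeostatic median lay below theirs. Of 27 disease-associated microglia genes, 9 were higher, 11 lower and 7 did not pass (10 and 11 adjusted over the list alone; adjusted p = 0.997). The median was -0.07 and the mean 0.15, and camera and fry gave opposite directions. Ch25h, which makes 25-hydroxycholesterol (3.07), and lysozyme Lyz2 (1.80, from 2814 ± 162 to 9818 ± 983 CPM) rose, and osteopontin Spp1 (-1.09) and Gpnmb (from 325 ± 4.78 to 163 ± 1.25 CPM) fell. Of 18 lysophospholipid receptors and LysoPS metabolism genes, 4 were higher and 3 lower (5 and 4 adjusted over the list alone; adjusted p = 0.923). They included the acyltransferase Lpcat2 (1.17) and the lysophosphatidic acid receptors Lpar6 (-0.70) and Lpar1 (-0.50), and 11 did not pass. Lpar1 was not called without mock replicate 1 (adjusted p = 0.0660) or mock replicate 2 (0.0837).

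Of 33 gene models for 32 lysosome and phagocytosis genes, 14 were higher, 5 lower and 14 not past the threshold (15 and 6 adjusted over the list alone). The acid lipase Lipa (1.27), the Fc receptor chain Fcer1g (1.93) and the integrin Itgb2 (1.62) rose. The integrin Itgam has 2 overlapping models whose counts were split unevenly between libraries. The sum of both was 157 ± 2.53 CPM in mock and 595 ± 7.17 CPM after LysoPS. The list's median was 0.18 and its adjusted p 0.00197, or 0.518 with an estimated correlation. Astrocyte markers had a median of -0.83 and general microglia and macrophage genes, which include Fcer1g, Itgb2 and Itgam, one of 1.05.

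Lipid synthesis genes fell. Of 25 cholesterol synthesis and SREBP2 target genes, 20 were lower and none higher (21 and 0 adjusted over the list alone), with a median of -0.59. They included the SREBP regulator Insig1 (-1.08, from 115 ± 5.72 to 54.3 ± 1.15 CPM) and the isomerase Idi1 (-0.84, from 85.1 ± 0.442 to 47.6 ± 1.67 CPM). The adjusted p was 6.9e-10, and 0.257 with an estimated correlation. Of 19 LXR target genes, 11 were lower and 3 higher (12 and 3 adjusted over the list alone), with a median of -0.42. The desaturases Scd1 (-1.03) and Scd2 (-0.70) and the lipid carrier Apoe (-0.57, from 2518 ± 45.2 to 1698 ± 11.1 CPM) fell, and the exporter Abcg1 (0.84) rose. That list had an adjusted p of 0.00764, and 0.279 with an estimated correlation. The astrocyte markers fell in the same libraries (median -0.83).

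Several stress and metabolic groups rose. Of 20 NRF2 antioxidant genes, 13 were higher and 1 lower (13 and 2 adjusted over the list alone), with a median of 0.72. Haem oxygenase Hmox1 rose from 293 ± 30.6 to 1711 ± 178 CPM (2.54) and ferritin heavy chain Fth1 from 2689 ± 200 to 10969 ± 1507 CPM (2.03), beside Abcc1 (1.70) and glutathione reductase Gsr (1.43). Of 19 unfolded protein response genes, 10 were higher and none lower (13 and 0 adjusted over the list alone), with a median of 0.48, and the smallest p-values were those of Herpud1 (1.27), Sdf2l1 (1.13) and the chaperones Hyou1 (0.68) and Hsp90b1 (0.46). Of 26 integrated stress response and ATF4 target genes, 12 were higher and 2 lower (14 and 2 adjusted over the list alone), with a median of 0.41, including Cebpb (2.27), Gdf15 (3.37), Mthfd2 (1.23) and Trib3 (1.71). Of 28 glycolysis and hypoxia-inducible genes, 11 were higher and none lower (13 and 1 adjusted over the list alone), with a median of 0.25, including adrenomedullin Adm (3.33), hexokinase Hk2 (1.37), Ero1l (1.13) and Ndrg1 (0.86). Adjusted p-values for these 4 lists were, in that order, 3.18e-08, 1.96e-05, 9.86e-05 and 0.000281. With an estimated correlation the adjusted p-values were 0.279, 0.257, 0.518 and 0.385. In the same libraries the median was -0.83 for astrocyte markers and 1.05 for general microglia and macrophage genes.

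Ribosomal protein genes rose by small amounts, and most respiratory genes did not pass. Of 30 ribosomal protein genes, 20 were higher and none lower (23 and 0 adjusted over the list alone), with a median of 0.36 and an adjusted p of 1.3e-06, or 0.518 with an estimated correlation and 0.113 by fry. Their median was 0.19 with the trend on length and GC content removed. Beside them, astrocyte markers had a median of -0.83 and general microglia and macrophage genes one of 1.05. Rps6 (0.46), Rps27a (0.49), Rps23 (0.45) and Rpl4 (0.43) each lost their call without mock replicate 1 or without mock replicate 2 (adjusted p from 0.0522 to 0.0915). Of 30 oxidative phosphorylation genes, 3 were higher and 27 did not pass (1 higher adjusted over the list alone), with a median of 0.16. They were Cox5a (0.74), Cyc1 (0.31) and Atp5b (0.24), and Uqcrb stood at 0.32 without passing. Uqcrb did pass with the replicate number as a block (adjusted p = 0.0201), in DESeq2 (0.0199), without a filter (0.0395), with robust dispersion (0.0474), over gene models with stable read assignment (0.0262) and without LysoPS replicate 2 (0.0344). With the trend on length and GC content removed its log2 fold change was 0.02 (adjusted p = 0.818). Cyc1 and Atp5b lost their call without either mock library or LysoPS replicate 1 (adjusted p from 0.0935 to 0.264). The call of that list (adjusted p = 0.0229) was lost with an estimated correlation (adjusted p = 0.684) and without mock replicate 2 (0.204) or LysoPS replicate 1 (0.231). It was also lost by fry (0.211), over gene models with stable read assignment (0.163), under a stricter filter on low counts (0.0518) and with the trend on length and GC content removed (0.415, with a median of 0.01). Of 18 heat shock genes, 4 were higher and 1 lower (4 and 1 adjusted over the list alone; adjusted p = 0.162), among them Hspd1 (0.58), Stip1 (0.41), Ahsa1 (0.37) and Hspb8 (-0.38). The last 3 were not called without either mock library (adjusted p from 0.0565 to 0.182), nor was Ahsa1 without LysoPS replicate 1 (0.0620). None of 28 proliferation genes passed, also when adjusted over the list alone, with Mcm5 (0.31), Mcm3 (0.30), Bub1 (0.31) and Tyms (0.30) nearest to it (list adjusted p = 0.696). Without adjustment 4 of them had an edgeR p under 0.05, and 3 passed in DESeq2 and 0 in limma-voom. With the replicate number as a block Mcm3 (0.0356) and Mcm5 (0.0357) passed, and both also did with robust dispersion (0.0489 and 0.0429), over gene models with stable read assignment (0.0300 and 0.0253) and with the trend on length and GC content removed (0.0250 each). Mcm5 passed with DESeq2 size factors (0.0488), without a filter (0.0494) and without LysoPS replicate 2 (0.0305). Bub1 passed over stable gene models (0.0341), with the trend removed (0.0497) and without LysoPS replicate 1 (0.0491). None of 13 mitochondrially encoded genes passed either, also when adjusted over the list alone (list adjusted p = 0.743), with mt-Nd1 at 0.19, mt-Nd6 at -0.50, mt-Nd3 at -0.16 and mt-Nd5 at -0.10. Of these 13 genes, 3 had an unadjusted edgeR p under 0.05, and 2 passed in DESeq2 and 1 in limma-voom. With the replicate number as a block mt-Nd1 (0.0206) and mt-Nd6 (0.00497) passed, as they did without a filter (0.0153 and 0.0192) and over gene models with stable read assignment (0.0465 and 0.0193). mt-Nd1 also passed with DESeq2 size factors (0.0476) and, barely, without LysoPS replicate 2, and mt-Nd6 without LysoPS replicate 1 (0.0332). With the trend removed mt-Nd3 (0.00521), mt-Nd5 (0.0478) and mt-Nd6 (0.0230) passed, while mt-Nd1 went from 0.19 to -0.02 (adjusted p = 0.707).

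**Figure D2:**
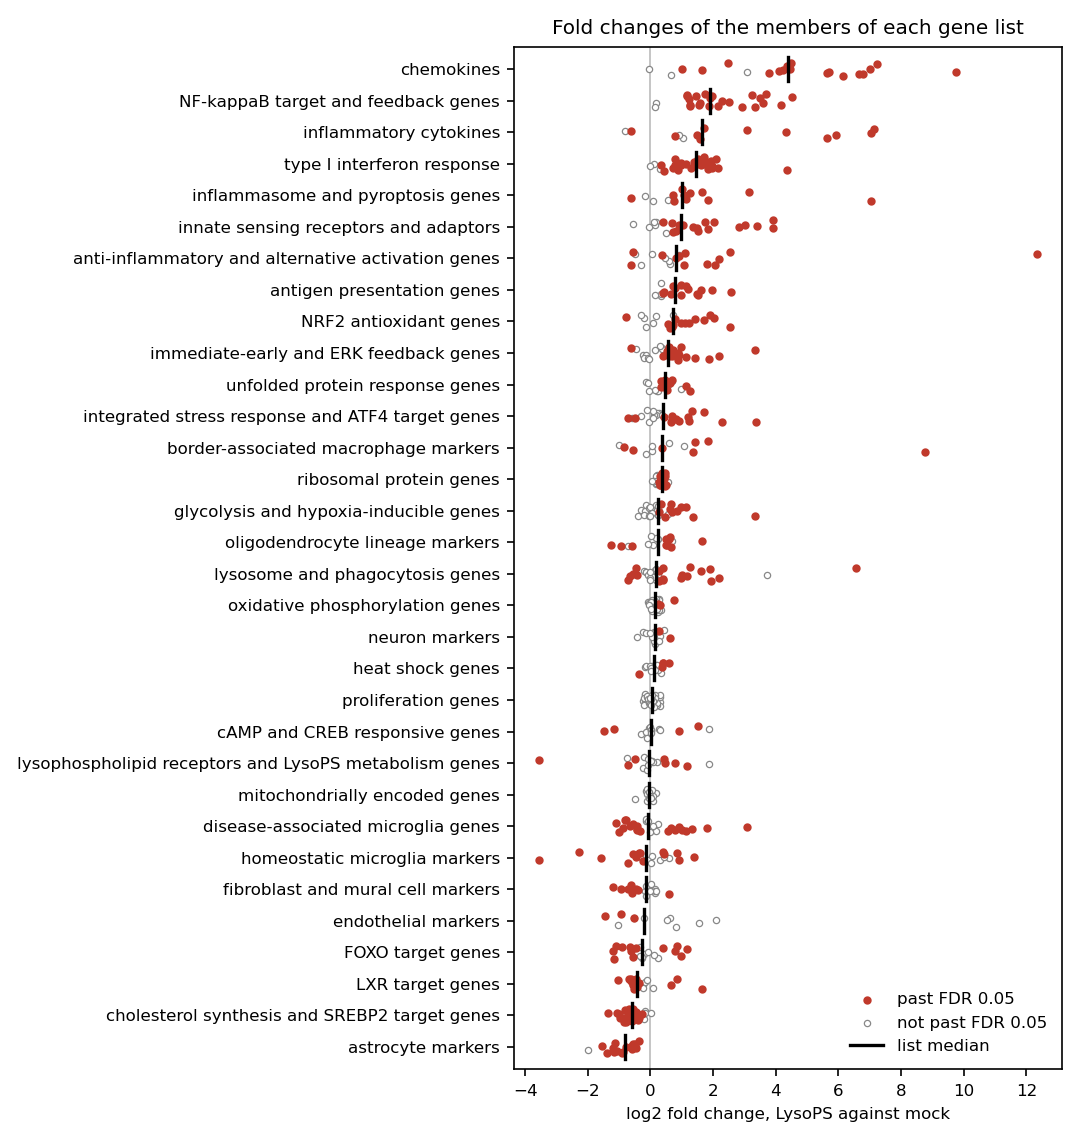
Log2 fold changes (LysoPS against mock) of the tested members of 32 gene lists; points are genes, red where the adjusted p was under 0.05, and black bars are list medians. Medians run from -0.83 for astrocyte markers to 4.40 for chemokines; fitted values of genes without mock counts (Il10, Cxcl11, Cd209f) depend on the prior count and are not bounds.

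Some astrocyte and fibroblast markers were detected at high levels. The astrocyte filament gene Gfap was the highest of the 4 named astrocyte markers, at 5827 ± 203 CPM in mock and 2790 ± 156 CPM after LysoPS (log2 fold change -1.06). Of 18 astrocyte markers, 16 fell and none rose (18 lower adjusted over the list alone), including Sparcl1 (-0.90), the folate enzyme Aldh1l1 (-1.13) and Aldoc (-1.55). The list's adjusted p was 1.54e-12, and 0.318 with an estimated correlation. Of 18 fibroblast and mural cell markers, 8 fell and 1 rose (9 and 1 adjusted over the list alone), with a median of -0.15. Fibronectin Fn1 fell from 4658 ± 49.7 to 3098 ± 126 CPM, decorin Dcn by 0.57 on the log2 scale, Mgp by 0.95 and Islr by 1.21. This list's adjusted p was 0.0124, and 0.341 with an estimated correlation. Of 13 border-associated macrophage markers, 5 rose and 2 fell (6 and 2 adjusted over the list alone), with a median of 0.38, among them Clec12a (1.83), Ms4a7 (1.42) and Pf4 (1.35), and Cd209f was at least 34.9-fold higher. Its adjusted p was 0.0167, and 0.443 with an estimated correlation and 0.0819 under a stricter filter on low counts.

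Of 17 oligodendrocyte lineage markers, 7 were higher and 3 lower (9 and 4 adjusted over the list alone; adjusted p = 0.335), with Cldn11 (-0.93), Bcan (-1.25) and Cnp (-0.58) down. Of 11 endothelial markers, 3 were lower and 8 did not pass (3 lower adjusted over the list alone; adjusted p = 0.353). These were Kdr (-1.45), Cdh5 (-0.93, from 301 ± 7.08 to 158 ± 16.3 CPM) and Slco1a4 (-0.52, implied length varying by 1.29 times), and Tek stood at -1.02 without passing, though it passed over gene models with stable read assignment (adjusted p = 0.0364). Slco1a4 was not called without either mock library or LysoPS replicate 1 (adjusted p from 0.0842 to 0.193). The median was -0.19 and the mean 0.09, and over gene models with stable read assignment the median was -0.92 (adjusted p = 0.00617). That set was chosen partly for close replicates, so p-values from it may be too small. Of 18 neuron markers, 2 were higher (1 adjusted over the list alone; adjusted p = 0.191), Stmn2 (0.63) and Elavl3 (0.29), and Gad2 (0.16) and Stmn3 (0.19) did not pass. Elavl3 was not called when any 1 library was left out (adjusted p from 0.0724 to 0.262) or without a filter (0.0563). Only 3 granulocyte and monocyte markers had enough counts, too few for a list test. Camp had no mock counts and was at least 21.1-fold higher, S100a8 (3.43, adjusted p = 0.0621) and Plac8 (-0.24, adjusted p = 0.794) did not pass, and 2 were higher adjusted over the list alone. S100a8, with 0 and 6 counts in mock replicates 1 and 2, did pass in DESeq2 (adjusted p = 0.0156) and without a filter (0.0244). Its log2 fold change was 2.64 without mock replicate 1, 2.57 without LysoPS replicate 1 and 4.00 without LysoPS replicate 2.

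**Figure D3:**
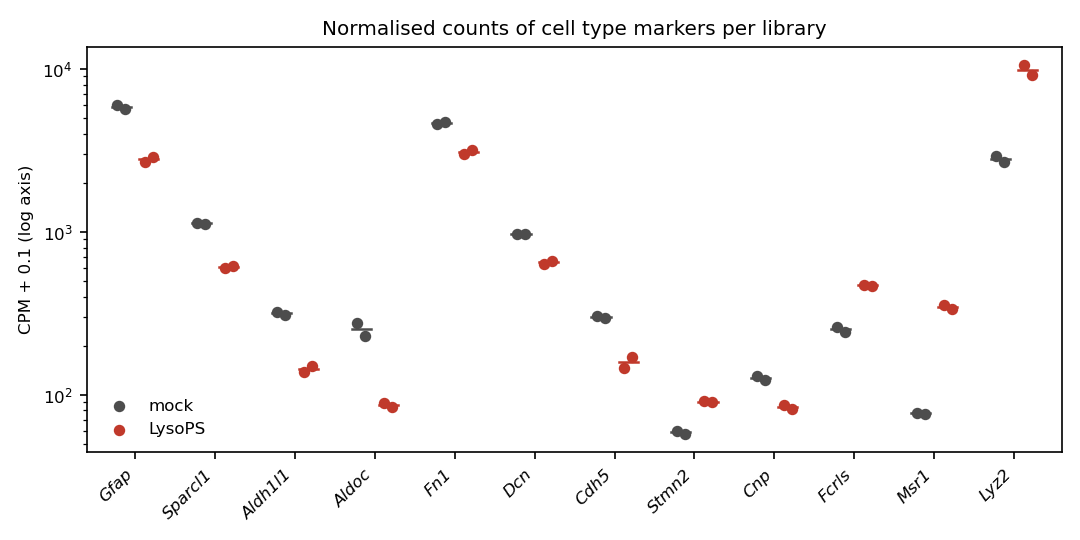
CPM of 12 cell type and microglial markers in each library on a log axis after adding 0.1, mock in grey and LysoPS in red; points are libraries and lines are the means of 2. Gfap goes from 5827 to 2790 CPM, while Lyz2 goes from 2814 to 9818 CPM.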

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

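The length and GC trend, the stable gene models and the removal of mitochondrial copies were chosen after seeing the data. Of 4854 changed genes, leaving out 1 library at a time gave 2165 to 5356, with 1161 to 2768 higher and 986 to 2588 lower; the low counts came without a mock library, and in each such fit the lone library of its group is assumed to vary like the other group. Testing against a 1.5-fold change left 1064 genes (683 higher, 381 lower), which the stricter null itself explains. The count ranged from 4399 to 5870 under the other alternatives, lowest with the stricter filter and highest with the trend removed, and the median log2 fold change of all genes moved by less than 0.1 in each. Among the 32 tested lists and 153 named gene models no called value changed sign, and the signs of the other genes were not compared. With an estimated correlation 0 of 32 lists passed, against 21 with the preset one and 19 by fry. The self-test's changed sets were called either way, but its genes were drawn independently. It therefore says nothing about lists whose genes are correlated. Leaving out a library gave 20 or 21 lists. The mitochondrially encoded list passed once the trend was removed (median -0.21, adjusted p = 0.00460), and the cause was not tested. The replicate numbers are shared between groups, but the labels do not say that they mark a shared culture. The replicate differences correlated at r = 0.145 across 12554 genes, and same-numbered libraries lay on the same side of the second principal component. A shared culture or batch can therefore not be excluded. With the replicate number as a block, 5433 genes changed (2797 higher, 2636 lower) and 21 lists passed, and the pairing was not used. Counts of genes such as Nos2 and Camp were low, the effect of depth was not tested, and the self-test recovered 19.7% of 1.5-fold changes. That rate comes from a simulation with 137 calls, against 4854 in the data, so it may not apply to this comparison.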

Other observations

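Gene families were formed by symbol stem, and that test was set before its result was seen; the tests for the other patterns in this part were chosen after the results were seen. Of 194 stems with 10 or more tested members, 28 passed camera, 18 higher and 10 lower, and 0 passed with an estimated correlation (adjusted p = 0.814). The stems described here were picked after the results were seen, and no list by function was tested. Of 26 Cfap genes, which encode cilia and flagella associated proteins, 18 fell and none rose (median log2 fold change -0.66, adjusted p = 1.21e-07). Of 16 axonemal dynein heavy chain genes (Dnah), 11 fell (median -0.87), and of 15 intraflagellar transport genes (Ift), 9 fell (median -0.44). Examples, named after their values were seen, were Cfap54 (73.2 ± 3.51 to 34.2 ± 5.26 CPM), Dnah9 (64.7 ± 1.62 to 34.4 ± 4.71 CPM) and Ift122 (56.8 ± 1.59 to 38.4 ± 0.284 CPM). These fell in the same libraries as the astrocyte markers.

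Some stems with roles in protein synthesis or turnover passed as higher and others did not. Of 55 translation initiation factor genes (Eif), 26 rose and none fell (median 0.27, adjusted p = 9.71e-05), with Eif2s2 going from 145 ± 6.24 to 223 ± 6.24 CPM. Of 10 Utp genes, which act in ribosome assembly, 7 rose (median 0.56), with Utp4 at 0.81. Of the proteasome genes, 6 of 10 Psmb and 7 of 14 Psmd genes rose (medians 0.38 and 0.29). The stems Eef (adjusted p = 0.215), Mrps (0.225), Ube (0.127) and Usp (0.451) did not pass, nor did Fbxo (0.0600), whose median was -0.20. With an estimated correlation the adjusted p of Eif, Utp, Psmb and Psmd was 0.814 each. In the same libraries the median was -0.83 for astrocyte markers and 1.05 for general microglia and macrophage genes.

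The rise of cytokine, chemokine and NF-kappaB genes could come from a larger share of microglia or macrophages in the LysoPS cultures. General microglia and macrophage genes, a list written after some of its values were seen and sharing 10 genes with the preset lists, also rose: 22 of 31 gene models were higher and 3 lower (median 1.05), with Aif1 rising by 2.33 on the log2 scale, Csf1r going from 336 to 441 CPM and C1qa from 318 to 436 CPM. The inflammatory genes detected in mock rose by more, with a median of 2.30 over 55 genes, a difference of 1.25 (two-sided permutation test across genes, p = 0.0018). That test treats genes as independent, but the estimated inter-gene correlation was 0.221 for cytokines, 0.663 for chemokines and 0.222 for NF-kappaB genes. Its p may therefore be too small and does not decide the question. The larger rise and the falls of Trem2 and Fcgr3 argue only weakly against a larger share as the whole cause. Removing the trend on transcript length and GC content kept 50 of 50 calls, which argues against that trend. An activation of the cells by LysoPS stays open as a hypothesis, as does a partial shift in cell shares and, for sensing, inflammasome and antigen presentation genes (medians 0.98, 1.02 and 0.79), a larger share alone. No library tests whether the response needs Gpr34.

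The fall of astrocyte markers may reflect dilution by RNA of other cells, a loss of astrocytes or a change within them. Dilution alone would lower fibroblast and mural cell markers alike, but the astrocyte median of -0.83 lay below theirs of -0.15 (difference -0.68, two-sided permutation test across genes, p = 8.00e-05). That test treats genes as independent, while the estimated inter-gene correlation of the astrocyte markers was 0.476, so its p may be too small. Neuron markers had a median of 0.15, with 2 higher and 0 lower of 18. Oligodendrocyte lineage markers had a median of 0.24, with 7 higher and 3 lower of 17. Neither list fell as a whole, as an equal dilution of all these cells would require. Endothelial markers had a median of -0.19, with 0 higher and 3 lower of 11. Of 18 fibroblast and mural cell markers, 8 fell and 1 rose, and Islr (-1.21) and Mgp (-0.95) fell further than the astrocyte median. A partial dilution is therefore not excluded. Fold changes differed between the markers (Cochran's Q of 268 with 17 degrees of freedom), but this decides nothing about a smaller astrocyte share, since a marker that other cells also express would fall less and the errors rest on 2 libraries per group. All 16 calls remained after the trend on length and GC content was removed. Partial dilution, fewer astrocytes, changed expression within them or a mix of these stay open. Gfap at 5827 CPM in mock shows that astrocyte RNA was plentiful in the mock cultures.

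Some genes differed over 4-fold between replicates of the same group after 0.1 CPM was added to each value: 75 of 12627 genes with a mean of at least 5 CPM, 42 in mock and 42 in LysoPS with 9 in both. Cx3cr1, the microglial fractalkine receptor, read 132, 13.4, 176 and 19.5 CPM in mock replicates 1 and 2 and LysoPS replicates 1 and 2, and Sh3pxd2a read 322, 27.6, 19.0 and 171. The highest of 100 Poisson draws held 0 such genes, which argues against counting noise alone for the 75. Libraries that may be separate cultures can differ by more than counting noise, so the draws do not tell the cause. A candidate explanation is reads assigned to other transcript or gene models in some libraries: 53.2% of these genes with a measurable implied length had a shift over 1.2 times, against 12.6% of the others (odds ratio 7.92, Fisher's exact test, p = 2.22e-14), and 56% against 23.3% overlapped another model on the same strand. Of the 75 genes, 5 were called changed: Acod1 and Fpr2, named above among the largest rises, and Marco, Saa3 and Gm21982. Cx3cr1 and Tlr4 were not called. Levels of the 75 genes in single libraries are uncertain.

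A trend of fold changes on transcript length was weak (Spearman's rho -0.145 across 12614 genes, which are not independent replicates). The choroid plexus gene Ttr had a log2 fold change of 2.85.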
